A study of Mus musculus with 8 samples.

How the data were processed

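Bulk RNA-seq was made from 4 mouse cell lines derived from genetically engineered models of lung squamous cell carcinoma (LUSC), with 2 libraries per line and 8 libraries in all. The lines were named PL1, PL12, PLA and PLA4. The labels set PL beside PLA lines and the series concerns loss of ACKR3, an atypical chemokine receptor. They do not spell out the letters, so the lines PLA and PLA4 are called the PLA lines and PL1 and PL12 the PL lines, and the level of Ackr3 serves as a check of these names. Nothing in the labels says that the 2 libraries of a line came from separate cultures, so p-values that rest on them measure the spread between these libraries, which may be technical. Per the labels' protocols, total RNA was taken with a column kit, cDNA was made with the SMARTer PCR method and libraries with Nextera XT.

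The authors deposited expected counts per gene, that is, estimated counts that need not be whole, and TPM (transcript abundance scaled to a fixed total per library) for the same genes, per the file headers. Per the submitters' processing notes, FastQC, STAR, RSEM and DESeq2 were used with the GRCm38 genome build, without versions. The annotation release is not given in the sources used here. The TPM columns the authors deposited sum to the same total in every library and keep no depth. The deposited expected counts held 55487 genes, and 14.2% of the values were not whole. They were rounded to whole numbers before any test. Coordinates were taken from GENCODE mouse release 21 on GRCm38. Of the gene identifiers, 54435 matched it with their version and 55227 without it.

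The line was treated as the unit of replication for the comparison of PLA and PL lines. Counts were summed over the 2 libraries of each line and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling and filterByExpr with default settings (minimum count 10, minimum total count 15), which left 18859 genes. Adjusted p is by Benjamini-Hochberg throughout, with a threshold of 0.05. A second test used the 8 single libraries with 1 mean per line and 4 residual degrees of freedom on 18648 genes. In it, a gene was counted where adjusted p passed the threshold with the same sign in each of the 4 comparisons of a PLA line with a PL line. The same count was taken for the other 2 ways of setting 2 of the lines against 2. The same fit compared PL12 with PL1 and PLA4 with PLA. Standard errors of log2 fold changes were obtained from the quasi-likelihood F statistic. CPM values are counts scaled to library size with TMM factors, and correlations and principal components used log2(CPM + 1).

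A set of 30 gene lists was tested with camera on the 4 summed profiles, with a preset correlation of 0.01 between genes, and with an estimated correlation and with fry beside it. The designs, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Ackr3, Stk11 and a further gene that is not reported here. It took the 12 largest rises and 12 largest falls between the families among genes called on summed profiles, with all libraries of a family above those of the other, a mean of at least 5 CPM and a plain gene symbol. Where fewer than 12 passed, places were filled with genes called in all 4 line comparisons, ranked by the smallest of their 4 absolute log2 fold changes. It further took 4 members per list by smallest p on summed profiles, members needed to describe a list, and, within each family, the 4 largest rises and falls among called genes with a mean of at least 5 CPM. No gene was called on summed profiles, so every place was filled from the second test.

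Depth ran from 48857912 to 142458240 counts per library, so a floor of 3 counts corresponds to 0.0614 CPM in the shallowest library and 0.0211 CPM in the deepest. Floors and counting intervals (95%, exact binomial) cover counting error only, since the libraries carry no molecular identifiers that could be used here. The tests were run on simulated data with the observed depths. Each gene was given the same spread in all lines. In the simulation of single libraries, lines of a family had the same mean. The real lines differ in spread and within a family, so the false calls below do not tell how many real calls are false. For the PLA and PL line comparison on 18859 genes, summed profiles recovered 3% of 100 genes changed 4-fold and 52% of 100 changed 16-fold, with 1 false call. For the genes called in all 4 line comparisons on 18648 genes, 37% and 63% were recovered with 0 false calls. For the gene lists, camera with the preset correlation found a list of 30 genes shifted 4-fold (adjusted p = 7.51e-24) and with an estimated correlation missed it (adjusted p = 0.212). The genes of that list were drawn at random and simulated without correlation, so the preset held there by construction. That run does not show whether the preset holds for the lists of real genes. For the 8 real lists that passed with the preset, the estimated correlations lay above it.

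Alternatives were other scalings, DESeq2 1.42.0, no filter on low counts, other units of replication, the replicate number as a block, the deposited TPM, a minimum fold and leaving out each library or line. Alternatives chosen after seeing the data were leaving out pairs of libraries of PL1 and PLA4, limma voom with a quality weight per line, and fry as an alternative count.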

Results

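Expression was measured in 4 murine LUSC lines, 2 of the PL family (PL1, PL12) and 2 of the PLA family (PLA, PLA4), with 2 libraries each. The PL1 libraries held 88993889 and 107042123 counts, those of PL12 48857912 and 107564327, those of PLA 125621332 and 120258506, and those of PLA4 132170387 and 142458240. Between 11986 and 12493 genes reached 1 CPM per library, and mitochondrial genes took 1.55% to 2.84% of counts.

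Ackr3 was measured first, since it checks the line names. It encodes an atypical receptor that scavenges the chemokine CXCL12 and adrenomedullin. Ackr3 (ENSMUSG00000044337.5, GRCm38 chromosome 1, 90203980 to 90216751) was nearly silent in the PLA lines. PLA held 0.0487 and 0.0254 CPM and PLA4 0.387 and 0.228 CPM in replicates 1 and 2. PL1 held 86.3 and 33.2 CPM and PL12 25.3 and 26.3 CPM. The line means were 0.169 ± 0.186 CPM in the PLA lines and 41.0 ± 21.0 CPM in the PL lines (SD, n = 2 lines each), a 242-fold lower level, or -7.92 on the log2 scale. Ackr3 fell in each of the 4 line comparisons (largest adjusted p = 0.00374, edgeR). On summed profiles its log2 fold change was -7.91 ± 1.37 (SE, adjusted p = 0.852, edgeR). In the deposited TPM the libraries held 0.22, 0.17, 1.61 and 1.25 TPM in PLA and PLA4 against 45.6, 19.6, 12.6 and 13.8 TPM in PL1 and PL12, and the log2 ratio of family means was -4.82. Gene-level values do not show from which exons the remaining counts came.

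**Figure D1:**
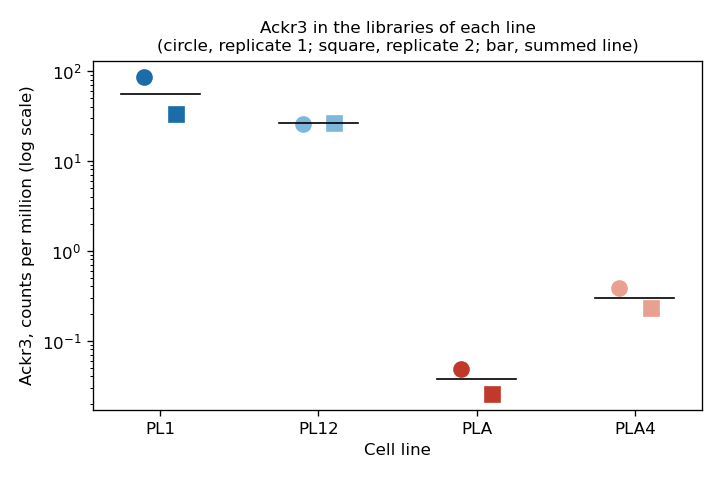
Ackr3 in CPM (vertical log axis) in each library of the 4 lines (horizontal axis), with a bar for the summed line. The PLA and PLA4 libraries sit at or below 0.387 CPM and the PL1 and PL12 libraries at or above 25.3 CPM.

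Stk11, which encodes the kinase LKB1, is a tumour suppressor often deleted in such models. Stk11 (ENSMUSG00000003068.17, chromosome 10, 80115803 to 80130682) stood at 21.8 and 26.1 CPM in PLA and PLA4 and at 21.6 and 19.3 CPM in PL1 and PL12 (log2 fold change 0.23 ± 0.333, adjusted p = 0.916, edgeR). These gene-level values do not show whether some of its exons were deleted.

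The lines differed strongly from each other and did not group by family. Correlations of log2(CPM + 1) across genes, which are not independent replicates, were 0.923 to 0.948 between lines of the same family and 0.916 to 0.967 between families. PL1 and PLA4 were the closest pair of lines, with a mean r of 0.960. The libraries of PLA (r = 0.999) and PL12 (r = 0.997) were close, with 8 and 64 genes over 2-fold apart. Those of PL1 (r = 0.978) and PLA4 (r = 0.974) were not, with 1174 and 1416 such genes. The PLA libraries differed by more than counting error, with reads taken as independent (chi-square per degree of freedom 8.19), and were kept as 2 libraries, which does not show that they were separate cultures.

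**Figure D2:**
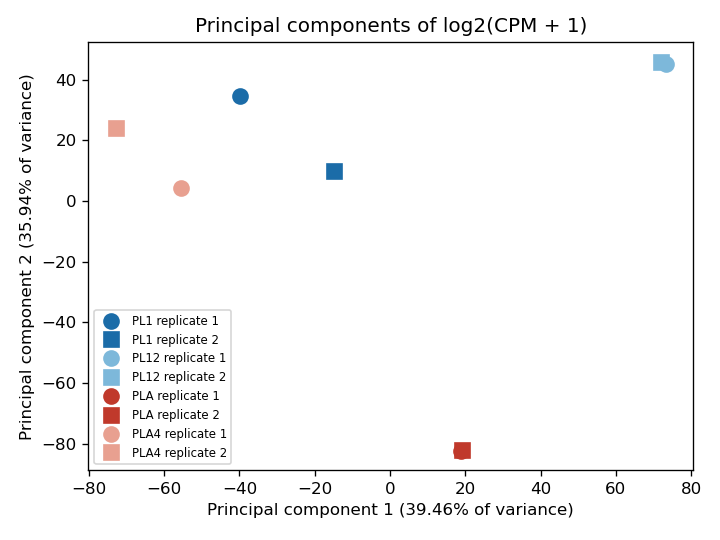
Principal components 1 and 2 of log2(CPM + 1), which hold 39.5% and 35.9% of the variance, with 1 point per library. PL12 and PLA each form a tight pair, while PL1 and PLA4 libraries lie on the same side and further apart within a line.

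The comparison of PLA with PL lines asks what accompanies ACKR3 loss. Ly6k, a surface protein of the Ly6 family, was at 75.3 and 48.8 CPM in PLA and PLA4 and had 0 counts in the PL lines, at least 7400-fold higher against a floor of 3 counts over the family, or 4858-fold without PLA4 replicate 1. The desmosomal cadherin Dsc3 was at 6.46 and 35.4 CPM against 0.0298 and 0 CPM in PL1 and PL12, a 1405-fold difference that was 741-fold without PLA4 replicate 2. Trim29, an epithelial gene of squamous tissue, rose 6.25-fold, and Tst, a mitochondrial sulfurtransferase, 12.9-fold. In the other direction, the RNA-binding oncofetal gene Igf2bp1 was 439-fold lower in the PLA lines, the ETS factor Etv4 26.8-fold, and the EGFR ligand Areg 15.1-fold.

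These genes were called in all 4 line comparisons, with the same sign each time. Of 18648 genes, 372 met this, 229 higher and 143 lower in the PLA lines (edgeR). All 372 had every library of a family above every library of the other. Over all genes 2935 (15.7%) were separated in this way. Chance would separate 2.86% if the 8 libraries were independent, which libraries of a line are not, and 33.3% if those of a line were alike. The other 2 splits separated 1384 and 3437 genes. The median of the smallest absolute log2 fold change was 1.06 for genes that were higher and 0.97 for genes that were lower. The same count was 118 for PLA and PL1 against the other lines and 734 for PLA and PL12 against PLA4 and PL1, so the family split was not the largest of the 3. It moved to 50 and 48 without PL12 replicates 1 and 2, to 39 and 36 without PLA replicates 1 and 2, and to 763 without PLA4 replicate 2.

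On summed profiles, where the line is the replicate, edgeR called 0 of 18859 genes (lowest adjusted p = 0.852), and 867 had an unadjusted p under 0.05, 4.60% of those tested. DESeq2 called 348 on the same profiles, 192 higher and 156 lower, against 157 and 770 in the other 2 splits of the lines. On simulated data with 18859 genes, edgeR's test on summed profiles recovered 3% of 4-fold and 52% of 16-fold changes.

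**Figure D3:**
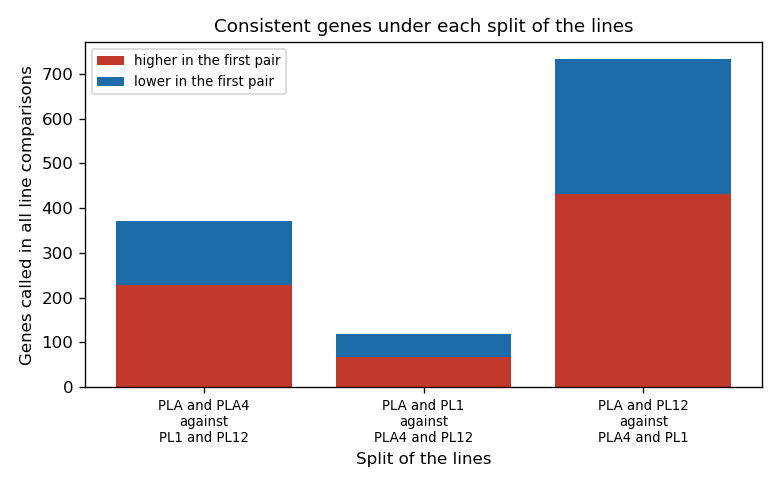
Number of genes called in all 4 line comparisons (vertical axis) for each of the 3 ways of setting the lines in pairs (horizontal axis), split by direction. The split of PLA and PLA4 against PL1 and PL12 holds 372 genes, and that of PLA and PL12 against PLA4 and PL1 holds 734.

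Among the other genes higher in the PLA lines were enzymes and a transporter. Ces1d, a carboxylesterase, was at 29.8 and 6.87 CPM in PLA and PLA4 against 0.208 and 0.230 CPM in PL1 and PL12 (83.6-fold). Cyp27a1, the sterol 27-hydroxylase, was at 6.35 and 22.9 CPM against 0.00992 and 0.224 CPM. Slc16a3, the lactate exporter MCT4, rose 41.2-fold and Hacd4, a very long chain acyl-CoA dehydratase, 26.7-fold. Ablim3, an actin-binding protein, rose 62.2-fold, Kctd14 38.4-fold, Rhov 16.4-fold, and H60c, a ligand of the receptor NKG2D, 15.7-fold. The fold of Kctd14 was 20.9 without PLA4 replicate 1 and 58.4 without replicate 2, that of Slc16a3 26.5 without PLA4 replicate 1, and that of Ces1d 138 without PL1 replicate 2. Largest adjusted p over the 4 comparisons ran from 0.00152 for Cyp27a1 to 0.0474 for Ly6k in edgeR.

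Among the other genes lower in the PLA lines, Il18rap, a subunit of the IL-18 receptor, fell 6.94-fold, and Ulbp1, another NKG2D ligand, stood at 32.7 and 2.67 CPM against 161 and 136 CPM. Ctla2b fell 11.8-fold, Svip 6.92-fold and Igsf9b 22.8-fold. Fosl1, an AP-1 subunit, fell 4.79-fold, Rrm2, a subunit of ribonucleotide reductase, 3.57-fold, and the protease inhibitor Slpi 3.79-fold. Over 16 alternative settings, Ackr3, Cyp27a1, Igf2bp1, Etv4, Il18rap and Ulbp1 passed in each, and 18 of the 24 named genes missed the threshold in at least 1. None of the 24 changed sign, but they were chosen with every library of a family above those of the other, which largely fixes the sign. All 24 also met a 2-fold minimum in each comparison. Their ranking by the smallest log2 fold change (lowest 1.58, for Slpi) set this in advance. Of the 24, Igsf9b passed in the fewest settings, 7 of 16, and Tst and Ctla2b passed in 8. Ly6k passed in 8 settings (adjusted p 5.92e-07 to 0.367) and Areg in 9 (8.46e-07 to 0.207).

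**Figure D4:**
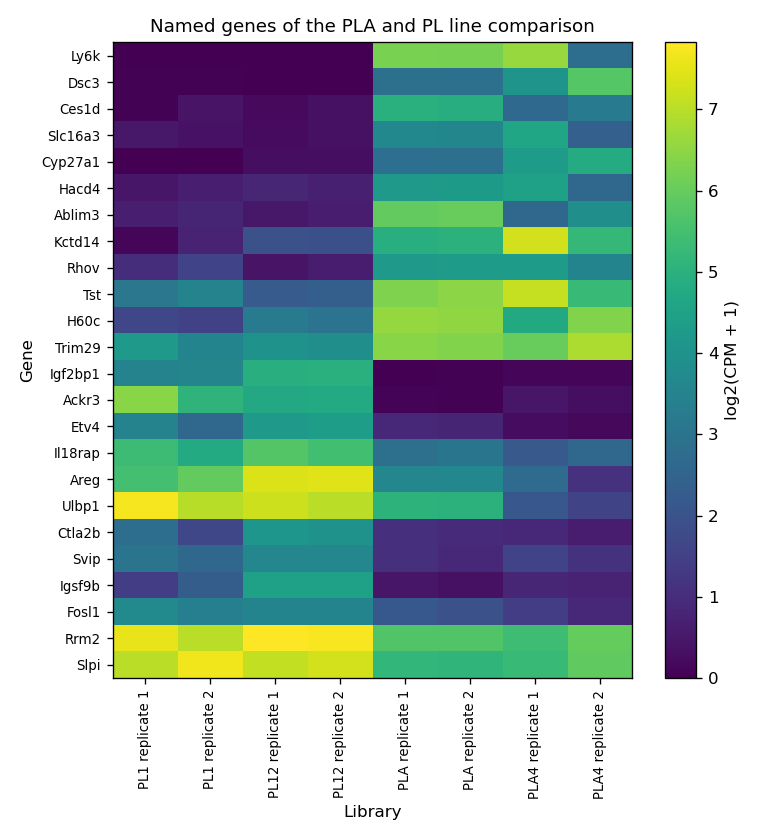
log2(CPM + 1) of the 24 named genes (rows) in the 8 libraries (columns), on a colour scale. The 12 upper genes are brighter in the PLA and PLA4 libraries and the 12 lower genes in the PL1 and PL12 libraries, while PLA4 replicates 1 and 2 differ for Ly6k, Kctd14 and Areg.

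Genes of the cell cycle were lowest in PLA, and PLA4 lay nearer to the PL lines. Of 34 S phase genes, 0 had a positive log2 fold change, with a median of -1.04 (camera adjusted p = 1.11e-15, and adjusted p = 0.789 with an estimated correlation). At the share over all genes (372 of 18648, either direction), 0.678 members of this list would be called in all 4 comparisons. Rrm2, Mcm3, Mcm6, Cdc6, Cdt1 and Chaf1b, 6 genes in all, were called lower in all 4 comparisons, and 7 when adjusted over the list alone. This count moved by over 1.5 times in 12 of 16 alternatives, from 0 with any 1 library of PL12 or PLA left out to 22 without PL1 replicate 1 and PLA4 replicate 2. Mcm3 stood at 21.9 CPM in PLA, 87.0 in PLA4, 171 in PL1 and 136 in PL12. Of 30 G2 and M phase genes, 0 were positive, with a median of -1.43 (camera adjusted p = 1.26e-17, and adjusted p = 0.789 with an estimated correlation). Kif23, a kinesin of cytokinesis, was called lower in all 4 comparisons, 1 gene over all genes and 1 when adjusted over the list alone. The share over all genes would give 0.598 called members, so 1 call is near that share. Kif23 passed in 10 of 16 alternatives, and the count moved in 11, from 0 with any 1 library of PL12 or PLA left out to 21 without PL1 replicate 1 and PLA4 replicate 2. The mean log2 CPM of the G2 and M list was 3.77 and 3.75 in PLA, 5.60 and 6.29 in PLA4, 6.75 and 6.15 in PL1 and 7.02 and 6.95 in PL12, so PLA4 replicate 2 lay above PL1 replicate 2. That of the S phase list was 3.86 and 3.84 in PLA, 5.06 and 5.46 in PLA4, and 5.57 to 5.99 in the PL libraries. Mki67 was at 45.2 and 238 CPM in PLA and PLA4 against 425 CPM in both PL lines.

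Genes that report ERK signalling were lower as a group. Of 24, 4 were positive, with a median of -1.29 (camera adjusted p = 2.69e-09, and adjusted p = 0.789 with an estimated correlation). The share over all genes would give 0.479 called members. Spry4, Etv4, Areg and Fosl1 were called lower in all 4 comparisons, and 5 members when adjusted over the list alone. The count moved by over 1.5 times in 9 of 16 alternatives, from 1 with any 1 library of PL12 or PLA left out to 7 without PL1 replicate 1 and PLA4 replicate 2, and Etv4 passed in 16, Fosl1 in 11, Spry4 in 9 and Areg in 9. On summed profiles 3 members passed when adjusted over the list alone, while 0 passed over all genes. Spry4, a feedback inhibitor of receptor kinases, was 146-fold lower, on 7 counts in the PLA lines and 679 in the PL lines, and 240.4-fold lower without PLA4 replicate 1, which held all of its PLA4 counts. Hmga2 stood at 0.850 and 2.10 CPM in PLA and PLA4 against 22.2 and 46.9 CPM, without passing in all 4 comparisons, and PL1 held 4.03 CPM in replicate 1 and 36.4 CPM in replicate 2. Egr1 stood at 434 and 97.3 CPM against 192 and 51.5 CPM, and PLA4 held 18.3 and 169 CPM in its libraries.

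Interferon response genes were higher mainly in PLA. Of 45, 44 were positive with a median of 1.58 (camera adjusted p = 7.75e-13, and adjusted p = 0.789 with an estimated correlation), yet 0 passed in all 4 comparisons, over all genes or adjusted over the list alone. The mean log2 CPM of the list was 6.41 in PLA, 4.12 in PLA4, 4.13 in PL12 and 3.87 in PL1. Gbp2, an interferon-induced GTPase, stood at 95.9 and 91.1 CPM in the PLA libraries and at 165 and 27.5 CPM in PLA4 replicates 1 and 2, against 20.5 to 25.2 CPM in the PL libraries. Isg15 stood at 161 and 150 CPM in PLA and at 38.3 and 5.72 CPM in PLA4, against at most 22.2 CPM in the PL libraries. Of 20 markers of immune cells, the 7 tested had a mean log2 CPM of 2.57 in PLA, -0.53 in PL1, 0.57 in PL12 and -0.56 in PLA4. PLA was not tested against the other lines for this list. In the list, Itgam, an integrin of myeloid cells, stood at 50.5 CPM in PLA and at 0.516 to 0.785 CPM in the other lines. Ly6g, a neutrophil marker, stood at 0.156 CPM in PLA and 1.80 CPM in PL12. Cd74, the MHC class II invariant chain, from the list of MHC class II presentation, stood at 26.1 CPM in PLA against 0.178 to 1.19 CPM in the other lines. Without the line PLA the interferon list missed the threshold (adjusted p = 0.362, in a range from 1.10e-35 to 0.789 over all alternatives). Between the libraries of PLA4, 33 members of the interferon list were over 2-fold lower in replicate 2, and between those of PL1, 26 were over 2-fold higher in replicate 2. In the list of MHC class I presentation, H2-T23 was called higher and Calr lower in all 4 comparisons, with 1 gene each way when adjusted over the list alone (camera adjusted p = 0.0583), and H2-T23 passed in 16 of 16 alternatives and Calr in 7. The share over all genes would give 0.439 called members in this list. The mean log2 CPM of this list was 7.10 in PLA, 5.03 in PL1 and 5.46 in PL12. PLA4 lay below both PL lines on summed profiles, at 4.62. Its replicates 1 and 2 stood at 5.10 and 3.83, and those of PL1 at 4.225 and 5.36. The order of PLA4 and PL1 thus depended on the library. The direction of the list turned without the line PLA.

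Squamous genes were higher as a group, and PL12 had the lowest levels. Of 36, 33 were positive with a median of 0.91 (camera adjusted p = 5.50e-08, and adjusted p = 0.789 with an estimated correlation). Dsc3 passed in all 4 comparisons, and 1 member when adjusted over the list alone. The share over all genes would give 0.718 called members, so 1 call is near that share. The split of PLA and PL12 against PLA4 and PL1 called 6 members, and that of PLA and PL1 against the other lines called 0. Trp63, the squamous lineage factor, stood at 27.3 CPM in PL12 against 374 CPM in PL1, 362 CPM in PLA and 346 CPM in PLA4. Krt5 stood at 308 CPM in PL12 against 3752 CPM in PL1, 6586 CPM in PLA and 5362 CPM in PLA4.

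Of 31 cytokines that recruit neutrophils and other myeloid cells, 10 were positive with a median of -1.11 (camera adjusted p = 6.81e-04, and adjusted p = 0.789 with an estimated correlation). The share over all genes would give 0.618 called members. The mean log2 CPM of this list was 2.02 and 1.97 in PLA4 and 3.895 and 3.91 in PLA. It was 4.37 and 4.38 in PL12 and 2.78 and 4.53 in PL1, so PL1 replicate 1 lay below PLA. PLA4 had the lowest levels for several of the cytokines. Cxcl5 stood at 587 CPM in PLA4, 2461 in PLA, 2060 in PL1 and 6665 in PL12, and Lcn2 at 25.9, 507, 525 and 1319 CPM, with 5.90 and 928 CPM in the PL1 libraries. Il18 alone passed in all 4 comparisons and was higher in the PLA lines, 3.22-fold, also when adjusted over the list alone, and it passed in 7 of 16 alternatives. The list missed the threshold in 4 of 11 alternatives, among them without the line PLA4 (adjusted p = 0.427) and without PL1 replicate 2 and PLA4 replicate 1 (adjusted p = 0.18), in a range from 5.85e-11 to 0.789. Of 28 genes of ATF4 and the unfolded protein response, 10 were positive with a median of -0.35 (camera adjusted p = 1.93e-03, and adjusted p = 0.789 with an estimated correlation). Manf and Pdia6, which act in the endoplasmic reticulum, were called lower in all 4 comparisons, and 2 members when adjusted over the list alone, while Trib3 stood at 67.7 and 4.09 CPM against 28.6 and 9.51 CPM, with 4.19 and 47.6 CPM in the PL1 libraries. The count of called members moved in 10 of 16 alternatives, from 0 with any 1 library of PL12 or PLA left out to 11 without PL1 replicate 1 and PLA4 replicate 2. This list missed the threshold in 5 of 11 alternatives, among them without the line PL1 (adjusted p = 0.252), without the line PLA4 (adjusted p = 0.743) and without PL1 replicate 2 and PLA4 replicate 1 (adjusted p = 0.51), in a range from 1.60e-06 to 0.789. Of 34 mesenchymal genes, 13 were positive with a median of -0.27 (camera adjusted p = 0.0487, and adjusted p = 0.789 with an estimated correlation), and 0 passed in all 4 comparisons or when adjusted over the list alone. The call was lost with the same direction in 7 of 11 alternatives, among them DESeq2's size factors (adjusted p = 0.0572), and the direction turned in 2, without the line PL1 (adjusted p = 0.237) or PLA (adjusted p = 0.844), in a range from 2.19e-10 to 0.856. Col1a1 stood at 143 CPM in PL1, almost all of it in replicate 2 (254 CPM against 0.575 CPM).

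With the preset correlation 8 of 30 lists passed, and 16 without the line PL12. For the 8 lists, the correlations estimated on the 4 profiles ran from 0.102 (myeloid cytokines) to 0.907 (G2 and M phase). All lay above the preset of 0.01, so the p-values with the preset assume less correlation than was estimated. With an estimated correlation or with fry 0 passed. Fry's test for change in either direction called 1 list, glycolysis (adjusted p = 0.0439). In that list Slc16a3 rose in all 4 comparisons, and 1 member rose and 1 fell when adjusted over the list alone. The share over all genes would give 0.459 members called in all 4 comparisons. Pkm stood at 837 and 1008 CPM against 1784 and 2013 CPM. Between the families, markers of other cell types did not pass, with camera adjusted p of 0.340 for immune cells, 0.448 for endothelium, 0.749 for fibroblasts and mural cells, and 0.635 for neuroendocrine cells. The count filter left 7 of 20, 8 of 15, 11 of 17 and 4 of 13 markers of these lists, and the rest were not tested. The fibroblast and mural list had a median log2 fold change of 0.42 and a mean of -1.18, and its test pointed down.

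The chemokine and adrenomedullin axis, which holds the ligands of ACKR3 and their receptors, did not pass as a list (camera adjusted p = 0.0781, 7 of 17 tested members positive, median log2 fold change -0.25). Ackr3 was its only member called in all 4 comparisons, 1 gene over all genes and 1 when adjusted over the list alone. The fall of Ackr3, which serves as the check of the line names, thus enters the result of this list. The list was not tested without Ackr3. Cxcl12 stood at 0.00841 and 1.19 CPM in PLA and PLA4 against 13.4 and 0.140 CPM in PL1 and PL12, with 0.253 and 23.6 CPM in the PL1 libraries. Adm, which encodes adrenomedullin, stood at 25.8 and 45.0 CPM against 51.2 and 4.23 CPM, and Ramp3, a co-receptor for adrenomedullin, at 7.12 and 11.8 CPM against 37.1 and 25.3 CPM. In lists that did not pass, the growth factor Tgfb2 (117 and 118 CPM against 52.9 and 18.9 CPM), Bhlhe40 (707 and 523 CPM against 286 and 303 CPM) and the aldehyde dehydrogenase Aldh3a1 (131 and 75.9 CPM against 22.9 and 15.1 CPM) rose in all 4 comparisons. Nrp1, a receptor for semaphorins and VEGF, fell (13.3 and 11.7 CPM against 27.2 and 25.4 CPM). Of 16 alternatives, Aldh3a1 passed in 12, Tgfb2 in 8, Nrp1 in 7 and Bhlhe40 in 6.

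**Figure D5:**
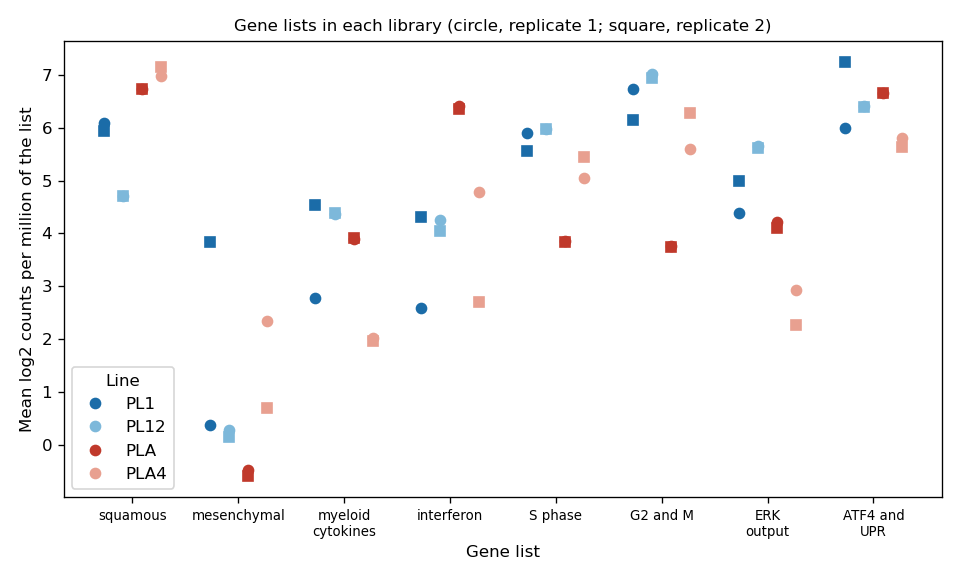
Mean log2 CPM (vertical axis) of the 8 lists that passed with the preset correlation (horizontal axis), with 1 point per library, coloured by line. PLA stands apart for interferon and cell cycle genes, and the libraries of PL1 and of PLA4 differ for the mesenchymal and interferon lists.

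Lines of the same family were compared to show how far lines differ without a difference in family. PL12 expressed genes that PL1 nearly lacked. Wnt7a, a Wnt ligand, had 5936 counts in PL12 and 2 in PL1 (ratio 3820, counting interval 1060 to 31600). Msln, the surface protein mesothelin, was at 468 CPM against 0.159 CPM, the claudin Cldn6 at 254 against 0.0943 CPM (0.138 and 0.0617 CPM in the PL1 libraries), and Krt19, a simple-epithelial keratin, had 206285 counts against 135 (ratio 1970, counting interval 1660 to 2350). Xlr3a and Cldn34c1 had 0 counts in PL12 and were at least 1040-fold and 411-fold higher in PL1, against a floor of 3 counts in the line. Zfp182 (ratio 912, counting interval 252 to 7540) and Galnt6 (ratio 591, counting interval 163 to 4880) were also higher in PL1. Both counts of Zfp182 and of Galnt6 in PL12 came from replicate 2. The ratio of Galnt6 was 312 without PL1 replicate 1 and 963 without replicate 2, and that of Krt19 3693 without PL1 replicate 2. Of 18648 genes, 4419 were called, 2090 higher and 2329 lower in PL12 (edgeR). The count was 763 and 804 without PL12 replicates 1 and 2, and 2049 and 2055 without PLA replicates 1 and 2.

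PLA4 and PLA differed as widely. Cntln and Prrg3 had 0 counts in PLA and were at least 1200-fold and 190-fold higher in PLA4. Tenm3 (ratio 2310, counting interval 790 to 11200) and Dcc, a netrin receptor (ratio 2200, counting interval 609 to 18200), were also higher in PLA4. Gdf10, a TGF-beta family ligand, was at 55.1 CPM in PLA against 0.0145 CPM in PLA4, where all its counts came from replicate 1 and the ratio was 1779 without replicate 2, and the transporter Slc47a1 at 95.2 against 0.0472 CPM. The Y-linked genes Eif2s3y (at least 1090-fold) and Kdm5d (ratio 2570, counting interval 461 to 102000) were higher in PLA. The bound for Prrg3 was 17.6-fold without PLA4 replicate 1 and 386-fold without replicate 2, and the ratio of Tenm3 was 1471 without PLA4 replicate 1 and 1196 without PLA replicate 2. All 3 counts of Tenm3 in PLA came from replicate 1 and the 1 count of Kdm5d in PLA4 from replicate 2, and the ratio of Kdm5d was 1347 without PLA4 replicate 1. Of 18648 genes, 5414 were called, 2635 higher and 2779 lower in PLA4 (edgeR). The count was 1079 and 1051 without PLA replicates 1 and 2, and 3503 and 3533 without PL12 replicates 1 and 2. For the single comparisons between families, 1593 genes were called for PLA4 against PL1, 5100 for PLA against PL1, 6709 for PLA4 against PL12 and 7035 for PLA against PL12.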

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

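The 3 tests of explanations in this part, for counting error and depth, cells of another line and fibroblasts, were chosen after the difference between libraries, or part of what they measure, had been seen. Each family's 4 libraries were compared for 7 quantities, 14 sets in all, and 2 sets held a library far from the other 3, where chance gives about 1 in 20. The 4 libraries come from 2 lines, so they are not independent. Ackr3 in PL1 replicate 1 was 86.3 CPM, against 25.3 to 33.2 CPM in the other PL libraries. PLA4 replicate 2 had 12200 genes at 1 CPM or more, against 12446 to 12489 in the other PLA-line libraries.

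The libraries of PL1 and of PLA4 differed far more than those of PL12 and PLA: PL1 replicate 2 was higher for Ltf (1030 against 4.95 CPM), Col1a1 (254 against 0.575 CPM) and Gpnmb (574 against 3.72 CPM), and PLA4 replicate 2 was lower for Tnfrsf11b (1.34 against 456 CPM), Cldn7 (0.741 against 155 CPM) and Vim (0.242 against 61.6 CPM). Counting error and depth are argued against, since the PL12 pair, the least equal in depth, had at most 0.0545 as many genes over 2-fold apart. Cells of another of the 4 lines are argued against by genes nearly absent from the sister library and abundant in the other line. Over 12 combinations, their median share was at most 0.0663 of the share that the risen genes would need. The risen genes were picked for their rise over the sister library, which raises the share needed. All 4 fibroblast genes in PL1 replicate 2, Col1a2 (0.176 CPM), Lum (0.0176 CPM), Col3a1 (8.48 CPM) and Dcn (10.7 CPM), lay under the 0.1 of the Col1a1 level that fibroblasts were assumed to bring, which speaks against them, but they stay open, since the limit for excluding them asked for 3 of the 4 below 0.02 of that level and 2 were. A difference in culture state or subclone was not tested, and the labels name none.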

How the results depend on the processing

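Leaving out 2 libraries together, voom with a weight per line and fry were chosen after seeing the data. Leaving out 2 libraries together left PL1 and PLA4 with 1 library each. The spread in those fits came from the closely matched PLA and PL12 pairs only. The cause of each shift below was not tested, except that fewer libraries, a changed threshold or another unit of replication enter by construction. With 8 libraries as independent replicates, libraries of a line count as replicates. The contrast of line means sets the lines against the spread between libraries of a line only. Neither count answers the family question with the line as the unit. For PLA lines against PL lines on summed profiles, edgeR's 0 calls became 348 with DESeq2, 1 without a filter, 160 with 8 libraries as independent replicates, 6206 with a contrast of line means and 1 with voom and line as a random block. They were 0 with each library or line left out, from 0 to 0, and the other scalings, TPM and a 1.5-fold threshold also gave 0. The 372 genes called in all 4 comparisons became 848 with DESeq2, 192 with a 2-fold minimum, and 105 with a weight per line (52 and 922 in the other splits). They were 36 to 763 with 1 library left out. Without PL1 replicate 2 and PLA4 replicate 1 they were 2072 (931 and 3149 in the other splits, 368 shared with the 372), and without PL1 replicate 1 and PLA4 replicate 2 they were 2446 (1408 and 2173, 368 shared). Leaving out 1 library gave 763 to 6128 calls for PL12 against PL1 and 1051 to 6618 for PLA4 against PLA. The 8 lists became 0 with an estimated correlation, 0 with fry, 13 without PL1 replicate 1 and PLA4 replicate 2, and 7 to 16 with a line left out. The mesenchymal list turned upward without PL1 (adjusted p = 0.237) and without PLA (adjusted p = 0.844), in a range with a line left out from 2.19e-10 to 0.844. MHC class I presentation turned downward without PLA (adjusted p = 0.0176), in a range from 5.38e-11 to 0.461. The log2 ratio of Ackr3 was -4.82 in TPM and -8.39 to -7.45 with 1 library left out.

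Replicate numbers did not pair the libraries, with correlations of deviations between lines from -0.194 to 0.0148. With a replicate block the family test on 8 libraries called 0 genes, 132 genes passed in all 4 comparisons, and 3177 and 4208 passed within the families.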

Other observations

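The tests of a loss of the whole Hoxb cluster in PLA4, of a loss confined to the Hoxb genes and of copy number shifts of any size were chosen after the result was seen, as was leaving out 2 libraries together, and the other tests of explanations in this part before. The explanation of a lost segment was narrowed to one that reaches the neighbouring genes after its test was run. The Hoxb genes and the genes of the other split were chosen after their values were seen. The split of PLA and PL12 against PLA4 and PL1 called 734 genes. Msln (130 and 468 CPM in PLA and PL12 against 0.127 and 0.159 CPM in PLA4 and PL1) and Plac8 (296 and 826 CPM against 4.14 and 9.09 CPM) were higher in PLA and PL12. Nox4, a superoxide-producing oxidase (17.3 and 5.25 CPM in PLA4 and PL1 against 0.00841 and 0.0255 CPM), the matrix protein Postn (13.6 and 9.19 CPM against 0.130 and 0.0766 CPM) and Smoc2 (59.0 and 25.5 CPM against 0.261 and 0.728 CPM) were higher in PLA4 and PL1. The lung lineage factor Nkx2-1 stood at 8.80 CPM in PL12 and at or below 0.0907 CPM in the other lines.

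Several Hoxb genes were present in the PL lines and near 0 in the PLA lines. Hoxb3 and Hoxb2 had 0 counts in the PLA lines, at least 961-fold and 179-fold lower against a floor of 3 counts over the family, and Hoxb4 was at 9.85 and 4.96 CPM in PL1 and PL12 against 0.0547 and 0.00726 CPM in PLA and PLA4. Hoxb9 (23.9 CPM in PLA4) and Hoxb8 (0.388 CPM in PLA4 against 0.397 and 3.05 CPM in PL1 and PL12) did not follow, and Igf2bp1 lies within 1 Mb of the cluster (chromosome 11, 95957163 to 96005940). Loss of a segment that reaches the neighbouring genes is argued against, since the 28 expressed genes within 1 Mb of the cluster had median log2 differences of 0.0524 in PLA and 0.220 in PLA4. Loss of the whole cluster in PLA4 is argued against by Hoxb9 at 23.9 CPM, while a loss confined to Hoxb genes stays open for PLA and for part of the cluster in PLA4, as 0 other expressed genes lay within 0.1 Mb of the cluster (96271457 to 96354691) and the nearest were Atp5g1, which ends at 96075670, and Snx11, which starts at 96767555.

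For the genes called between the PLA and PL lines, the 3 ways of setting 2 lines against 2 are too few for a share under 0.05; the real split gave 372 genes and the highest other 734, so 2 of the 3 gave as many. Without PL1 replicate 1 and PLA4 replicate 2 the real split was the largest. It was not without PL1 replicate 2 and PLA4 replicate 1. Both fits set PL1 and PLA4 against the spread of the PLA and PL12 pairs only. Those pairs had 8 and 64 genes over 2-fold apart, against 1174 in PL1 and 1416 in PLA4. These fits therefore do not rank the splits. Sex of the source animals is argued against, since PLA4 had Xist (299 CPM) and PLA, PL1 and PL12 had Ddx3y (14.8, 82.4 and 4.15 CPM), so that 2 of the 4 pairs of a PLA and a PL line shared their state. Depth is argued against (361 genes after thinning to 48857912 counts, 0.970 of the number). Gene length is argued against by a difference of 0.143 in median log2 fold change between the longest and the shortest of 5 length classes. A whole-chromosome shift of over 0.2 (log2) in all 4 comparisons is argued against, since no chromosome had such medians and 0 of the 372 genes lay on one. Chromosome 15 came near. Its medians were 0.131 and 0.206 for PLA against PL1 and PL12, and 0.433 and 0.423 for PLA4. Copy number shifts that fall under 0.2 in some of the comparisons stay open for part of the genes. Of the 372, 91, a share of 0.245, lay on chromosomes shifted their way at any size in all 4. The share of all genes on these gives 60.5, and the largest absolute median of such chromosomes was 0.433. Differences between the lines unrelated to ACKR3 and ACKR3 loss itself stay open too.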
